A study of Pyrus pyrifolia with 6 samples.

How the data were processed

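RNA from leaf buds of Japanese pear (Pyrus pyrifolia, cultivar Kosui) was measured on 6 one-colour Agilent arrays, 3 of dormant and 3 of released buds, each labelled with Cy3. Per the labels' protocols, the trees received ordinary orchard care and no treatment, total RNA was cleaned on a column and checked by capillary electrophoresis, and the labelled material was made with a linear amplification kit for low RNA input. Nothing in the labels says whether the replicates came from separate trees, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision of every value.

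The scanner files hold spot intensities in linear units. Per the file headers, the authors extracted them with Feature Extraction 9.5.3.1, with spatial and multiplicative detrending and replacement of low signals by surrogate values switched on. The array carries 37744 non-control spots, which are 18872 probes of 60 bases spotted 2 times each. Every spot has the description "Unknown" and no coordinate, so none of the 35 gene lists and 4 tissue marker lists fixed before the data were examined matched a probe (0 probes matched), and neither they nor the planned test of gene list shifts were run. Probe names start with DIT, NFR, NFW, NLE or NI4, followed by a clone number, and end in F, R or S. These codes are not explained in the sources used here. They serve as name classes, and names that differ in the last letter alone are taken as one clone. By that reading, for 9060 clones the array has an F and an R probe of different sequence, and for 752 clones a single S probe.

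The series also has a table of processed intensity values that the authors deposited for 9812 probes, those ending in R or S. Set against the scanner signals, its values are linear, equal to the mean of a probe's spots divided by a constant close to that array's 75th percentile over the listed probes, with a floor of 0.01. No centring of probes was found. Between 96.4% and 98.0% of the values above 0.05 lay within 1% of this rule. The column medians are 0.239, 0.221 and 0.228 for dormant replicates 1, 2 and 3 and 0.206, 0.212 and 0.212 for released replicates 1, 2 and 3. The tool that made the table is not given in the sources used here. Scale, centring and direction are known from this match, and the table serves as an alternative source of values.

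The log2 values reported here were computed from the deposited processed signal. Each array's 75th percentile over non-control spots was subtracted, spots with a population or uniformity outlier flag were left out, and the remaining spots of a probe were averaged on the log2 scale. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 15534 probes and removed 3338. Released and dormant buds were compared with limma 3.58.1 (lmFit and eBayes, group as the single term) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required a difference of at least 1 on the log2 scale. Of 200 probes changed in simulated arrays with the means and spreads of this comparison (15528 probes), limma recovered 76 of 100 changed by 1 and 89 of 100 changed by 2 on the log2 scale, with 8 false calls among 173. Those runs assume independent errors of normal shape and changed a far smaller share of probes than passed in the comparison itself. The adjustment depends on that share, so these rates need not carry over.

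Without gene names, at most 2 probes that rose and 2 that fell are named. By the rule fixed before the data were examined, they are the largest changes among probes past the test, well above background on all 6 arrays, not saturated in a whole group, and with every released array on one side of every dormant array. The name classes were chosen after the files were seen. They were compared with camera at a preset correlation of 0.01 on 1 probe per clone (the brightest on average, 8672 clones), with Benjamini-Hochberg adjustment over 15 overlapping classes, and again with an estimated correlation and with fry. Percentages per array were compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot go below 0.1.

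The header of each file gives its slide. The first slide held dormant replicates 1, 2 and 3 and released replicate 1, and the second held released replicates 2 and 3. The comparison was therefore also fitted with the slide as a block and within the first slide, where the single released array is assumed to vary like the dormant ones. The second slide holds released buds alone, so with the block too the difference is that of released replicate 1 from the dormant arrays. Released replicates 2 and 3 then add to the estimate of spread alone. A probe not well above background on any array of a group has only a bound there. Its "at least" fold is the mean log2 level of the other group over the mean of, per array, the higher of the lowest level well above background and the probe's own. Other alternatives were quantile and median scaling, scaling to 7 spike-in control probes, a percentile over probes detected on all arrays, normexp background correction with an offset of 50, other filters and a floor on low signals, flagged spots kept, other variance models, the deposited table, the replicate number as a block, and each array left out. Figures were drawn with matplotlib 3.10.9.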

Results

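The series compares gene expression in dormant and released leaf buds of Japanese pear. Buds of the dormant group were taken in early endodormancy, the phase in which growth is held back by the bud itself, in October 2008. Buds of the released group were taken in February 2009, at the stage the labels describe as breaking. Each group has 3 arrays and a single collection date, so bud stage cannot be told apart from date and season. The 75th percentile of the processed signal was 1952, 2963 and 2230 intensity units on dormant arrays 1, 2 and 3, and 1453, 1609 and 2013 units on released arrays 1, 2 and 3. The difference between groups did not pass an exact two-sided permutation test (p = 0.2, where 0.1 is the smallest possible).

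Arrays of one group resembled each other more than arrays of different groups. Pearson's r across the kept probes, which are not independent replicates, lay between 0.9886 and 0.9976 for the 6 pairs within a group and between 0.929 and 0.944 for the 9 pairs between groups. The closest pair, dormant replicates 2 and 3, had a between-array SD of 0.155 on the log2 scale, and the noise between duplicate spots gave 0.0924. This does not tell separate samples from repeat hybridisations of one, and each array was counted as the separate sample that the labels list.

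Released and dormant buds differed at 8248 of 15534 probes (53.1%) by limma with Benjamini-Hochberg adjustment. Signal was higher in released buds at 3685 probes and lower at 4563. Differences of at least 2-fold were found at 2988 probes, of which 1144 were higher and 1844 lower in released buds. Large changes were mostly falls, except at the brightest probes. Among the 3882 probes with the highest mean signal, 22 rose and 12 fell by 8-fold or more. Over all probes, 99 rose and 333 fell at this size, and with normexp background correction 52 rose and 96 fell. At 32-fold or more, 4 rose and 93 fell, against 1 and 13 with normexp, 15 and 92 without dormant replicate 3, and 1 and 106 without dormant replicate 1. These sizes include probes not well above background on some arrays of a group. Among probes well above background on all 6 arrays, 1060 rose and 1295 fell by 2-fold or more, against 1144 and 1844 of all kept probes. By 8-fold or more 73 of them rose and 146 fell, and by 32-fold or more 1 rose and 33 fell. The groups did not overlap at 9805 of 15528 probes (63.1%), where chance gives 10%. The share of changed probes that were higher, 44.7% with the main scaling, was 63.5% (5473 higher, 3140 lower) when arrays were scaled to their median and 17.0% (922 higher, 4488 lower) when they were scaled to the spike-in controls. Among changes of at least 2-fold this share was 38.3% with the main scaling, 54.7% (1689 higher, 1401 lower) with median scaling and 17.7% (711 higher, 3316 lower) with spike-in scaling, whereas falls of 8-fold or more outnumbered such rises with median scaling (283 against 129) and spike-in scaling (426 against 68) too. The median difference of all probes was -0.08 on the log2 scale with the main scaling, 0.15 with median scaling and -0.44 with spike-in scaling, so each direction given here is relative to the scaling. The spike-in controls stood 0.60 ± 0.37 above the 75th percentile on dormant arrays and 0.96 ± 0.17 above it on released arrays (log2, SD, n = 3), a difference that did not pass an exact two-sided permutation test (p = 0.2). Dormant replicate 1 stood lowest, at 0.19, against 0.89 and 0.73 on dormant replicates 2 and 3. Released replicates 1, 2 and 3 stood at 0.91, 1.15 and 0.83, so the gap between groups rested largely on dormant replicate 1. The shift to falls with spike-in scaling follows from this gap. With the slide as a block 5915 probes changed, 2867 of them by at least 2-fold. The differences in that fit rest on released replicate 1 against the dormant arrays, as they do within the first slide. Within the first slide, with 1 released array, 4467 changed, 2737 of them by at least 2-fold.

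The 2 probes named for their rise were NFW1_04_64mR and NLE1_06_75mF. The signal of NFW1_04_64mR (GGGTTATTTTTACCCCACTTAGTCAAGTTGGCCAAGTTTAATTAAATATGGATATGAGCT) rose from -1.06 ± 2.36 to 4.83 ± 0.11 on the log2 scale relative to the array's 75th percentile (SD, n = 3). Its difference was 5.89 (SE 1.09), or 59.1-fold, with an adjusted p of 0.0047 by limma. The F probe of otherwise the same name rose by 4.96. NLE1_06_75mF (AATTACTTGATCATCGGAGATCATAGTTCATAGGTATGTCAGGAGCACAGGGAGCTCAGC) rose from -4.07 ± 1.52 to 0.91 ± 0.15 (SD, n = 3), a difference of 4.98 (SE 0.71), or 31.5-fold, with an adjusted p of 0.00155 by limma, and the R probe of otherwise the same name rose by 4.76. The dormant arrays spread widely at these probes. NFW1_04_64mR stood at -3.41, -1.06 and 1.30 on dormant arrays 1, 2 and 3 against 4.71, 4.92 and 4.85 on the released arrays, and NLE1_06_75mF stood at -5.34, -4.47 and -2.39 on the dormant arrays. The size of both rises therefore rested on single arrays, and neither passed when the spread was estimated for each probe alone, without limma's pooling across probes. NFW1_04_64mR also did not pass on the first slide alone, with fewer arrays, where its difference was 5.77 (adjusted p = 0.0917 by limma). The log2 difference of NFW1_04_64mR was 4.71 without dormant replicate 1, 7.06 without dormant replicate 3 and 3.60 with array weights, and that of NLE1_06_75mF was 4.34, 5.81 and 3.25. The array weights did not converge, so 3.60 and 3.25 are not firm estimates. At 31 probes high in released buds, dormant replicate 3 exceeded the mean of the other dormant arrays. The excess had a median of 8.01% of the gap from that mean up to released replicates 2 and 3. With this share of released signal taken out of dormant replicate 3, the log2 difference was 7.44 for NFW1_04_64mR and 5.61 for NLE1_06_75mF. NFW1_04_64mR is itself 1 of the 31 probes that set the share. The share removed was nearly all of its signal on dormant replicate 3, so 7.44 hinges on the exact share and is not a firm size.

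The 2 probes named for their fall were NFR4_19_54mR and NFR1_14_21mR. NFR4_19_54mR (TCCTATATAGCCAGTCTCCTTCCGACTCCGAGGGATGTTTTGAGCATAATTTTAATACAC) fell from 2.89 ± 0.08 in dormant buds to -4.35 ± 0.32 in released buds (SD, n = 3). Its difference was -7.24 (SE 0.17), so that dormant buds were 150.9-fold higher, with an adjusted p of 2.73e-06 by limma. NFR1_14_21mR (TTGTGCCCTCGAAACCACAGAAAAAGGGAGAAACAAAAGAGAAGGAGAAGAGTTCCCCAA) fell from 1.43 ± 0.22 to -5.24 ± 0.29 (SD, n = 3), a difference of -6.67 (SE 0.18) in which dormant buds were 101.9-fold higher, with an adjusted p of 4.37e-06 by limma. The other probe of the same clone was not well above background on any released array for NFR4_19_54mR, with a level at least 19.96-fold higher in dormant buds. For NFR1_14_21mR it was well above background on 1 of the 3 released arrays and was lower in released buds, with no exact size. Both falls passed the test under all 26 alternatives that measured them, with log2 differences from -7.59 to -6.36 for NFR4_19_54mR and from -7.03 to -5.34 for NFR1_14_21mR, the smallest falls being those with normexp. The gene behind each of the 4 probes is not given in the sources used here.

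**Figure D1:**
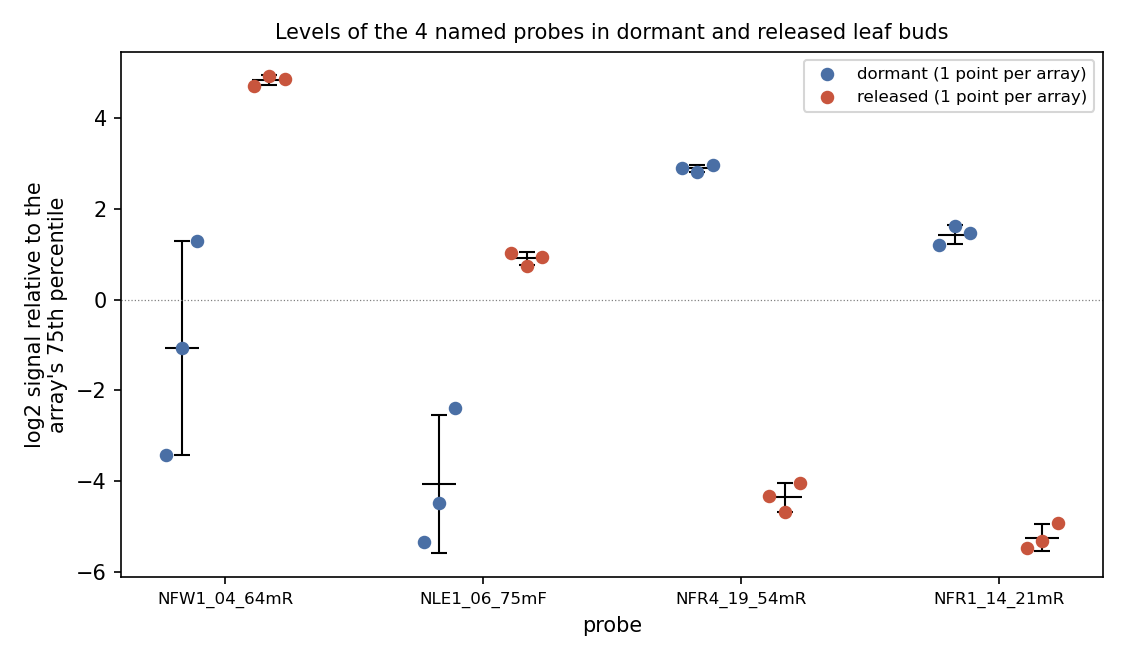
Level of each of the 4 named probes on each array (vertical axis, log2 signal relative to the array's 75th percentile), with dormant arrays in blue and released arrays in red. Horizontal marks are group means and bars are ± 1 SD over 3 arrays; the dormant arrays of NFW1_04_64mR spread from -3.41 to 1.30, while its released arrays lie between 4.71 and 4.92.

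Probes whose names differ in the last letter alone, F or R, were taken as 2 probes of one clone, which the sources used here do not state. Of 6862 clones with both probes kept, 1220 were higher in released buds at both probes, 1550 were lower at both, and 66 passed in opposite directions, which is 2.33% of those where both probes passed. The balance turned with the scaling, to 1899 clones higher and 1020 lower at both probes with median scaling and 302 and 1439 with spike-in scaling. Without dormant replicate 3, 35 clones passed in opposite directions. Independent calls would put 418.9 clones higher and 594.9 lower at both probes. Both probes passed with a difference of at least 2-fold for 371 clones that were higher and 574 that were lower. Across clones, which are not independent replicates, the differences of the F and R probes had a Pearson's r of 0.872 and a Spearman's rho of 0.813. At 1770 clones a single probe passed and at 2256 neither did.

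**Figure D2:**
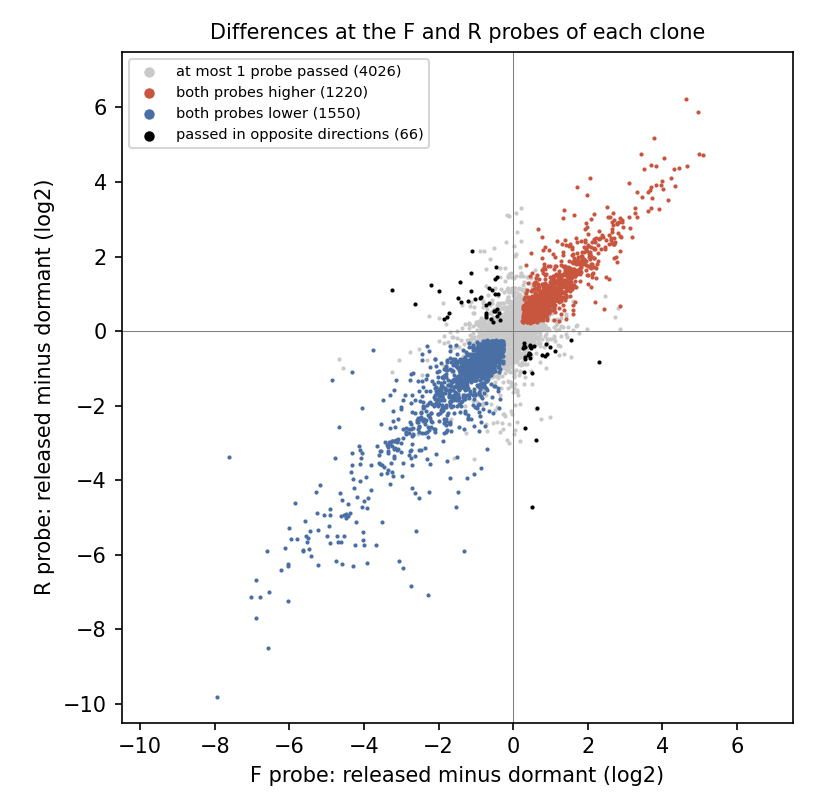
Difference between released and dormant buds at the F probe (horizontal axis, log2) and the R probe (vertical axis, log2) of 6862 clones, 1 point per clone. Red points are the 1220 clones higher in released buds at both probes, blue points the 1550 lower at both, black points the 66 that passed in opposite directions, and grey points clones where at most 1 probe passed.

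Among the classes of probe names, NLE1 had the highest share of clones that were higher in released buds, 41.5%. Of its 562 clones, 233 were higher and 102 lower, and its median difference was 0.28 above that of all other clones on the log2 scale (camera, adjusted p = 0.00064; adjusted p = 0.709 with an estimated correlation). NFW1 had 215 of 591 clones higher and 130 lower, with a median 0.22 above the rest (adjusted p = 0.0233; adjusted p = 0.709 with an estimated correlation). NFR3 had 249 of 1448 clones higher and 540 lower, with a median difference of -0.20 from the rest (adjusted p = 0.0317; adjusted p = 0.739 with an estimated correlation). Quantile normalization and normexp background correction ended the calls of NFW1, at 0.12 (adjusted p = 0.197) and 0.092 (0.0971), and of NFR3, at -0.12 (0.211) and -0.14 (0.0971), while NLE1 passed with both (0.0196 and 0.00812). Adjusted over the class alone, the counts were 235 higher and 106 lower for NLE1, 221 and 134 for NFW1, and 251 and 541 for NFR3. The balance of higher and lower clones also moved with the scaling. With spike-in scaling NLE1 had 93 higher and 84 lower and NFW1 turned to 57 higher and 110 lower, and with median scaling NFR3 turned to 403 higher and 383 lower. With the slide as a block, the median stood 0.24 above the rest for NLE1, 0.17 above for NFW1 and -0.23 from it for NFR3, with adjusted p of 0.0008, 0.0225 and 0.0112 by camera. Within the first slide these differences were the same by construction, since both settings compare released replicate 1 with the dormant arrays.

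The 4 wider classes did not pass. NFR as a whole had 1134 of 5121 clones higher and 1622 lower (adjusted p = 0.215 by camera). NFW had 468 of 1697 higher and 429 lower (adjusted p = 0.334), NLE had 455 of 1496 higher and 359 lower (adjusted p = 0.266), and DIT had 72 of 351 higher and 70 lower (adjusted p = 0.963). The other 8 numbered classes did not pass either, with adjusted p from 0.272 to 0.963.

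**Figure D3:**
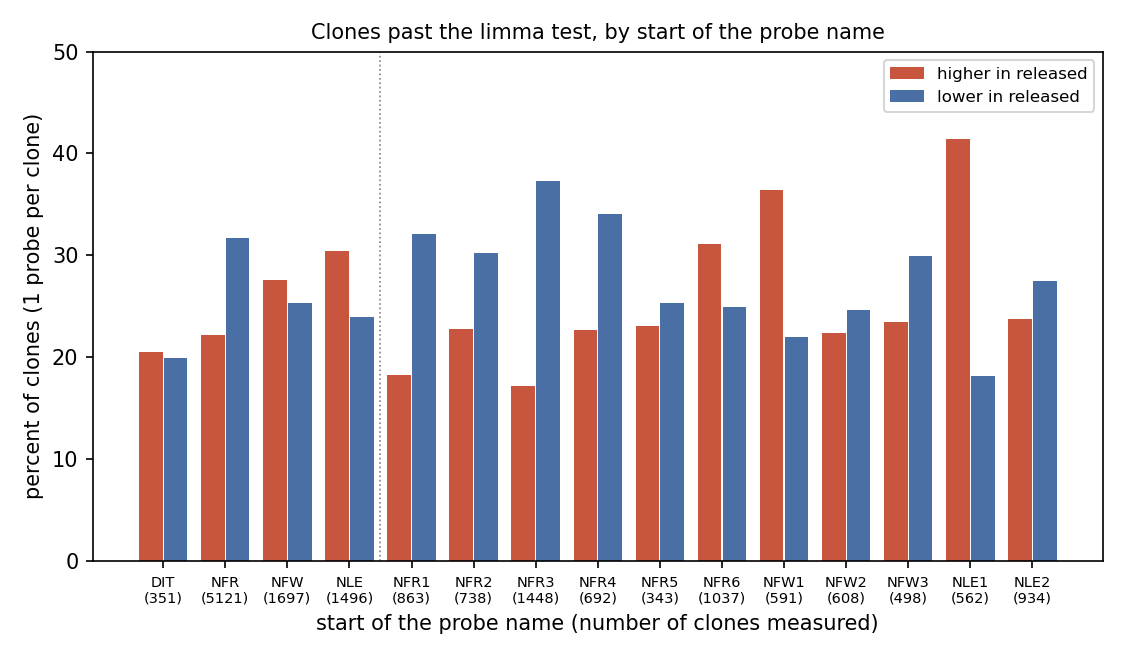
Percent of clones (vertical axis, 1 probe per clone) that passed the limma test as higher (red) or lower (blue) in released buds, for each start of the probe name (horizontal axis, number of clones in brackets); the 4 wider classes stand left of the dotted line. NLE1 had 41.5% of its clones higher and 18.1% lower, and NFR3 had 17.2% higher and 37.3% lower.

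Released buds had fewer probes well above background. The share of all probes was 83.8% ± 1.17 on dormant arrays and 78.4% ± 1.32 on released arrays (SD, n = 3; exact two-sided permutation test, p = 0.1, the smallest possible). With 1 floor on the scaled signal for all arrays, the difference in this share went from -5.47 to -2.50 percentage points (exact p = 0.2), and the groups overlapped. There were 538 probes, from 486 clones, that were well above background on all 3 dormant arrays and not on any released array. Of these, 391 passed the limma test, and 525 had a bound over 1, with a median of at least 1.92-fold higher in dormant buds. There were 22 probes, each from its own clone, with the opposite pattern. All 22 of them passed the test, with a median bound of at least 4.07-fold higher in released buds. With the common floor, 335 probes lost and 81 gained detection in released buds.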

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

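All class tests, clone counts, detection counts and the settings for spike-in scaling, the first slide alone, probe subsets, the common floor and the treatment of dormant replicate 3 were chosen after seeing the data; the others were fixed before. The planned test of gene list shifts, with its estimated correlation, fry and all-matched-probes alternatives, was not run because the files name no genes. Where no cause is given by fewer probes or arrays, the cause was not tested.

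The 8248 changed probes ranged from 6597 (without released replicate 2) to 8638 (without dormant replicate 1) when 1 array was left out, and were 5938 without dormant replicate 3 and released replicate 1 together. No probe called with the main setting was called in the opposite direction under another setting. Tests on fewer probes gave 4578 in the deposited table (2173 higher, 2405 lower; 1439 of at least 2-fold, 610 and 829), 4687 among its probes in the scanner files (2107, 2580; 1656, 637 and 1019) and 3530 among F probes (1565, 1965; 1333, 507 and 826). Spike-in scaling gave 5410 (922 higher; of at least 2-fold, 711 higher and 3316 lower). Its fit held 1 spread for nearly all probes (prior SD 0.40 with 36.7 degrees of freedom, against 0.15 and 2.27 in the main setting), so that its calls follow size, with none under 0.77 on the log2 scale. The first slide alone, with 4 arrays, gave 4467 (1906, 2561). Normexp background correction lowered the probes of at least 2-fold to 1907 (1002 lower), and with quantile normalization to 1905 (1003 lower). Array weights gave 11936, from weights that did not converge. The replicate block gave 7284. The deviations of same-numbered arrays correlated at 0.03, -0.15 and 0.15, and only the arrays numbered 3 correlated best with their own number. No pairing by number was detected, and so few arrays cannot exclude it.

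Clones higher at both probes were 1899 with median scaling, 810 with the slide block, 1833 with array weights, 778 with Welch's statistic, 302 with spike-in scaling, 565 on the first slide and 781 without dormant replicate 3 and released replicate 1. Clones lower at both were 1020 with median scaling, 1004 with normexp, 1026 with the slide block, 899 with Welch's statistic and 778 on the first slide. Clones in opposite directions were 31 with normexp, 25 with the slide block, 351 with array weights, 26 with Welch's statistic, 17 with spike-in scaling, 11 on the first slide, 39 without dormant replicate 3 and released replicate 1, and 35 (without dormant replicate 3) to 94 with 1 array left out.

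Over 18 alternatives run with camera, the adjusted p of the classes against the rest ran from 3.64e-05 to 0.709 for NLE1, 0.00667 to 0.709 for NFW1 and 0.0105 to 0.739 for NFR3, and calls were lost as follows. NFW1 stood at 0.12 with quantile normalization, 0.092 with normexp, 0.12 with both, and 0.16 to 0.24 with 1 array left out (adjusted p = 0.075 without dormant replicate 1). NFR3 stood at -0.12, -0.14 and -0.089 in the same settings, at -0.20 with spike-in scaling (adjusted p = 0.0734), and at -0.22 to -0.18 with 1 array left out (0.075 without dormant replicate 1, 0.0893 without released replicate 1). With an estimated correlation the differences, 0.28 for NLE1, 0.22 for NFW1 and -0.20 for NFR3, did not pass. With fry, which does not compare a class with other clones, NLE1 (adjusted p = 0.00271), NFW1 (0.00504) and NFR3 (0.00504) passed. Classes that camera did not call passed fry too. They were NFR, with a class median of -0.10 (adjusted p = 0.00495), NFR1 (0.00495), NFR2 (0.0272) and NFR4 (0.00504). DIT, not called, turned from -0.12 to 0.084 with normexp and 0.087 with the slide block and on the first slide.

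Signal over background limits the detection counts. Probes gained and lost were 81 and 335 with a common floor, 94 and 353 with that floor without dormant replicate 3, 40 and 376 with the floor after spike-in scaling, and 10 and 320 with the positive-and-significant flag. With 1 array left out, 22 to 43 were gained (43 without dormant replicate 2, 36 without released replicate 1) and 554 to 672 were lost. The difference in the share of probes well above background was -5.47 points, -2.50 with the common floor (exact p = 0.2), and between -5.99 and -4.14 in the other settings run. The highest correlation between groups was 0.944, and 0.967 with no filter on dim probes. NFW1_04_64mR and NLE1_06_75mF kept their direction and no longer passed with Welch's statistic (adjusted p = 0.098 and 0.0665, the highest over 26 and 25 alternatives, of which the lowest were 2.3e-12 and 9.24e-13 with spike-in scaling). NFW1_04_64mR also did not pass on the first slide (0.0917), with a difference of 5.77.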

Other observations

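The splits of the arrays, the tests of dormant replicate 3 for a common share and for the spread of shares, and the counts by signal level were chosen after the results were seen; the tests of the slide, of the neighbouring array and of detection were set before theirs, except that the interval of the detection ratio was added after its value of 4.136 was seen.

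The balance of rises and falls changed with the level of a probe. When the probes were divided into 4 groups of 3882 by their mean signal over all 6 arrays, 519 probes of the lowest group were higher and 1203 lower in released buds by limma, and 266 and 770 were so by at least 2-fold. In the group with the highest mean signal, 1234 were higher and 906 lower, and 314 and 213 by at least 2-fold. By 8-fold or more, 24 were higher and 187 lower in the lowest group, and 22 were higher and 12 lower in the highest. The median difference ran from -0.32 in the lowest group to 0.06 in the highest. The filter kept 538 probes well above background on all dormant and no released arrays, against 22 of the opposite pattern. This favours falls among dim probes. Among probes well above background on all 6 arrays, 1060 were higher and 1295 lower by at least 2-fold, against 1144 and 1844 of all kept probes. The extent within the lowest group was not tested. With normexp background correction the lowest group turned to 570 higher and 323 lower with a median of 0.20, and with quantile normalization to 964 higher and 856 lower with a median of 0.02, so the direction among all calls at dim probes depended on both choices. Falls stayed ahead there with median scaling (777 higher, 962 lower), the slide block (415 and 859), the first slide alone (341 and 754) and spike-in scaling (209 and 1568). Among changes of at least 2-fold, falls stayed ahead in the lowest group in each of these 6 settings, with 425 and 560 for quantile normalization, 93 and 148 for normexp and 359 and 626 for median scaling. In the highest group quantile normalization, which makes the distributions of the arrays equal, gave 1100 higher and 1099 lower. In the same group normexp gave 1159 and 852, the slide block 880 and 621, median scaling 1816 and 527, and spike-in scaling 268 and 716.

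With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 split with as many changed probes as 8248, and the highest of the other 9 gave 0 by limma, 562 at an unadjusted p under 0.05 and 0 by Welch's statistic with Benjamini-Hochberg adjustment. For changes of at least 2-fold the real split gave 2988, again in 1 of the 10, and the highest other gave 0, or 144 at an unadjusted p. Each of the other 9 splits mixes dormant and released arrays, so the real difference enlarges the spread within its groups. Their low counts were therefore built in and do not show what unrelated groups would give.

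Released replicates 2 and 3 shared a slide with no dormant array, so part of the differences might have come from the slide. The 5936 probes called from dormant replicates 1 and 2 against released replicates 2 and 3 were measured again in released replicate 1 minus dormant replicate 3, which lay on the same slide. The slope of the second difference on the first was 0.8261, and 5720 probes had the same sign. The 95% bootstrap interval of the slope was 0.8135 to 0.8388 over probes, which are not independent, and leaves out the variation between arrays. This argues against the slide as the whole source of the differences. With the slide as a block 5915 probes changed, against 8248 without it, and 2867 against 2988 by at least 2-fold. The differences in that fit rest on released replicate 1, since the second slide holds no dormant array. Released replicate 1 had between-array SDs of 0.279 and 0.311 on the log2 scale to released replicates 2 and 3. Those 2 arrays, on the other slide, had 0.184 to each other. Dormant replicate 1 had 0.337 and 0.297 to dormant replicates 2 and 3 on its own slide. With 1 released array on the first slide, slide and sample cannot be told apart, and a slide part at single probes was not excluded.

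Dormant replicate 3 lay between the groups at probes high in released buds. Its excess over dormant replicates 1 and 2 was taken as a share of the gap from them up to released replicates 2 and 3. At 31 such probes from 25 clones, chosen without use of dormant replicate 3, the median share was 8.01% (10th to 90th percentile 5.23% to 9.60%). The median share of dormant-type signal in released replicate 1 was 0.00329% at 41 probes high in dormant buds. A candidate explanation is a small admixture of released-type signal, since 100% of the 31 probes had a share within 2-fold of the median. Whether it came from the neighbouring array, released replicate 1, cannot be told apart, because the slope on that array's own deviations was 0.9036 with an interval of 0.2214 to 1.504. Buds nearer to release would give shares that differ between probes, and the 90th percentile was 1.837 times the 10th, but a pool holding some buds at a later stage would also give 1 common share and stays open.

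Many more probes lost detection in released buds (538) than gained it (22), a ratio of 24.5. Fewer probes were well above background on the released arrays, though their 75th percentile was not lower on each of them (2013 on released replicate 3 against 1952 on dormant replicate 1). Their median signal was lower on each, at 229, 247 and 310 units on released replicates 1, 2 and 3. It was 367, 517 and 408 units on dormant replicates 1, 2 and 3. With 1 floor on the scaled signal the ratio fell to 4.136 (95% exact binomial interval 3.236 to 5.339). The intervals of these ratios treat probes as independent and leave out the variation between arrays. A value above 4 had been set in advance to speak against dimmer arrays, and 4.136 passes it, though not by more than its interval. With that floor the ratio was 3.76 without dormant replicate 3, and 9.4 after spike-in scaling, so the answer depends on the scaling too. Dimmer arrays may therefore account for part of the excess, and whether they account for all of it cannot be told apart. Released-type signal in dormant replicate 3, which would hide gains, is argued against, since the ratio was 21 without that array (interval 14.73 to 30.95). It was 12.9 without dormant replicate 2. A difference between the bud stages stays open and was not tested apart from these.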
